A study of Mus musculus with 7 samples.

How the data were processed

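Total RNA from mouse leukemia cells was labelled with biotin and hybridized to Illumina MouseRef-8 v2.0 BeadChips, per the labels' protocols. The samples fell into 2 groups from their titles, BRD7116 with 5 arrays and DMSO with 2. The chip of each array was taken from its description label. The scanner software and its version were not given in the sources used here.

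The authors deposited an intensity for each of 25697 probes on each array, not normalized between arrays per the file headers, and a detection p-value per probe and array. The lowest intensities lay far above 0, so no background appeared to have been subtracted. The authors also deposited processed values on the log2 scale, whose method was not stated. These had the same median, 7.52, in each of the 7 columns, as quantile normalization leaves, were not centred per gene, and followed the ranks of the deposited intensities. They were used as an alternative.

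Intensities were corrected for background with the distribution of negative controls inferred from the detection p-values, offset by 16, quantile normalized and taken to log2 (neqc in limma 3.58.1, R 4.3.3). Probes with a detection p under 0.05 on at least 2 arrays were kept, which left 8613. Probe names came from the platform annotation. They were checked through the gene identifier against a RefSeq table of assembly GRCm38.p6, used for names only, which changed 0 symbols. A single symbol was given for 23978 probes and none for 1719, and no probe had several. For each gene the probe with the highest mean over the 7 arrays was used, and unnamed probes were kept on their own, which gave 6969 features, 6473 of them named. No coordinates were printed because the files name no genome build.

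BRD7116 was compared with DMSO by lmFit and eBayes (limma, two-sided moderated test, no covariates), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. A probe not detected on any array of one group had only a bound there. Its fold was given as at least the bright group's mean over the dim group's mean of, per array, the higher of the lowest level among detected probes and the probe's own level. The 47 gene lists, the comparison, the naming rule and the alternatives, save those named below, were fixed before the data were examined. The 43 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists. The test was repeated with the correlation estimated from the data, with fry and on ranks.

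The genes named in the text followed a rule. It took the 12 genes with the largest rise and the 12 with the largest fall past the threshold with all treated arrays on one side of both controls. Where fewer passed, the places were filled in order of unadjusted p, and here all were. From each list described it took up to 4 members past the threshold, or otherwise the 2 with the highest mean level, and 10 regulators of leukemia were added in any case. Trim10, Junb, Klf6 and Hexim1 were named outside the rule, after their values were seen. The 17 lists described one by one, and the lists whose members are named, were chosen after the values were seen, and the other 26 are given together.

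The replicate numbers of the 2 groups were checked for pairing. BRD7116 replicate 1 shared its chip with DMSO replicate 2, and BRD7116 replicate 2 shared its chip with DMSO replicate 1, so that equal numbers lay on different chips and were not taken as pairs.

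The alternatives changed the background correction, the normalization, the detection filter, the treatment of several probes per gene, the prior and the weight of arrays, used the authors' values, blocked on chip or on replicate number, and left out each array in turn. Leaving out both arrays of the dim chip was added after the data were seen, once with the other 5 arrays normalized anew and once with the normalization over 7 arrays. The estimated correlation within the alternative fits that called a list was also added then. Where a setting moved the median of all genes by over 0.1, values were taken relative to that shift. Where a single control remained, it was assumed to vary like the treated arrays.

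The fit was tested on simulated data for the 7 arrays and 6969 features, with 200 genes changed, 100 by 2-fold and 100 by 4-fold, in 20 runs. With normal noise, given the SD of another gene of like level, 31.4% of the 2-fold and 75.7% of the 4-fold changes were recovered. Of the calls, 5.43% were false. With the real residuals put on the arrays in random order, these shares were 17%, 68% and 19.7%. The normal noise was added after this last share was seen. A list of 20 genes, all raised 2-fold, was found by camera at a p under 0.05 in all 20 runs of each kind. A list of 20 unchanged genes was found in 2 and 0 runs. The noise was drawn for each gene separately, so these counts do not cover lists of correlated genes or smaller shifts. Neither kind of noise placed the spread of the dim chip on its own arrays, so recovery in the real design may differ.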

Results

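The transcriptional response of mouse leukemia cells to BRD7116, a small molecule known here only by its code name, was measured by expression array. The cells were freshly isolated and labelled as leukemia stem cells. They were exposed for 6 h in suspension to 5 µM BRD7116 in 0.2% DMSO or to the DMSO vehicle. BRD7116 was assayed on 5 arrays and DMSO on 2 arrays, each with 25697 probes. The series is about small molecules that act on leukemia stem cells, and its single comparison asks which transcripts differed between compound and vehicle. The labels do not say that replicates were separate cultures or animals. The p-values therefore measure the spread between these samples, which may be technical.

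The 7 arrays came from 3 chips, and 1 chip gave far weaker signal. This dim chip held BRD7116 replicate 1 and DMSO replicate 2, on which 4585 and 4412 probes were detected. The other BRD7116 arrays detected 7470, 8451, 6946 and 7730 probes, and DMSO replicate 1 detected 6749. The brightest probe reached 4515 and 4704 intensity units on the dim chip and at least 27582 on each other array. After normalization, 61.1% of the variance lay along a component that set the dim chip apart from the others. A second chip held BRD7116 replicate 2 and DMSO replicate 1, and the third held only BRD7116 replicates 3, 4 and 5. The comparison was therefore also made within each chip that held both groups.

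**Figure D1:**
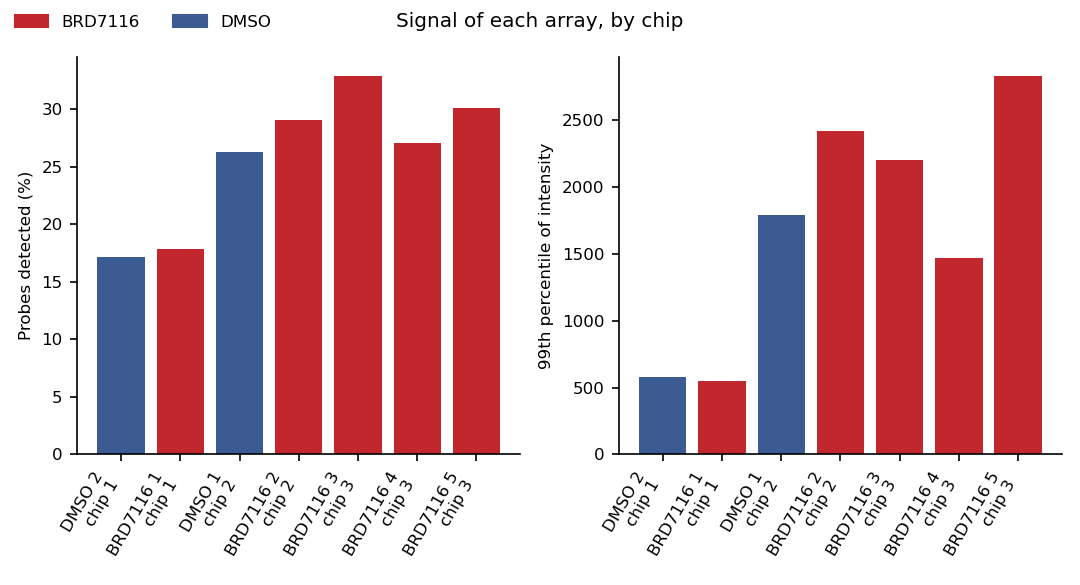
Signal of the 7 arrays, grouped by chip, as the percentage of probes detected (left) and the 99th percentile of probe intensity in scanner units (right); each bar is 1 array, red for BRD7116 and blue for DMSO. On chip 1, 17.2% and 17.8% of probes were detected, against 26.3% to 32.9% on the other arrays.

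Metallothionein 1, a metal-binding stress protein, had the smallest p-value. Mt1 was 2.75-fold higher with BRD7116, at 13.73 ± 0.06 (SD, n = 5) against 12.27 ± 0.12 (SD, n = 2) on the log2 scale. Its log2 fold change was 1.46 with a standard error of 0.16 and an adjusted p of 0.126. Klf2, a zinc finger transcription factor associated with quiescence in blood cells, was 2.91-fold higher (log2 fold change 1.54, standard error 0.23, adjusted p = 0.355), though it was detected on only 1 of the 2 control arrays. Its value depended on the background correction, with 0.81 for normexp, 0.57 without correction and 0.49 with the authors' values. Ddit3, which encodes the stress-induced transcription factor CHOP, was 2.72-fold higher (log2 fold change 1.44, standard error 0.28, adjusted p = 0.658). Within the dim chip the differences were 1.31 for Mt1, 1.61 for Klf2 and 2.15 for Ddit3, and within the second chip they were 1.48, 1.31 and 1.502. With chip as a block the values were 1.39, 1.46 and 1.82, and none passed. The authors' values gave 1.05 for Mt1 and 0.69 for Ddit3.

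The remaining genes that led the higher side had log2 fold changes of 1.398 for Esyt1, 1.33 for Tmem11, 1.42 for Tmco4, 1.19 for N6amt1 and 1.11 for Coa4. With the authors' values these were 0.58, 0.38, 0.46, 0.35 and 0.45, and without DMSO replicate 2 Esyt1 had 0.93, Tmem11 1.08 and Coa4 0.72. Leaving out 1 array took Tmco4 as low as 0.97 and N6amt1 as low as 0.83. Tmem11, Tmco4 and N6amt1 were each detected on only 1 of the 2 control arrays. Pink1, a mitochondrial kinase, was detected on all 5 treated arrays and on neither control, which bounded its difference at 1.39-fold or more. Nit2 was at least 1.17-fold higher and Zfp397 at least 1.01-fold higher by the same reasoning. Zfp27 was also undetected in both controls, and its level gave no bound above 1. These bounds rest on the background-corrected values. The authors' values gave log2 fold changes of 0.26 for Pink1 and 0.20 for Nit2, below their bounds, and 0.22 for Zfp397, which meets its bound. None of these genes passed the threshold.

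On the lower side, 2 genes detected on all 7 arrays stood out. Rnu6, the U6 small nuclear RNA of the spliceosome, differed by a log2 fold change of -1.01 with a standard error of 0.18 and an adjusted p of 0.633. Hba-a1, an alpha globin, differed by -0.92 with a standard error of 0.22 and an adjusted p of 0.658. Within the dim chip the differences were -0.93 for Rnu6 and -0.998 for Hba-a1, and within the second chip -0.99 and -0.80. The authors' values gave -0.73 for Rnu6 and -0.46 for Hba-a1. The other 10 genes that led the lower side lay close to background. Agbl3 (-1.31) and Tmem59l (-1.24) were each detected on 1 treated array, as were Ptger4 (-1.01) and Rsf1 (-0.75). Polb (-1.18) and Foxd3 (-1.58) were detected on 2 treated arrays, and Prss40 (-1.46) and Tmem138 (-0.65) on 3. Without DMSO replicate 2, Polb had -0.74, Foxd3 -0.87 and Prss40 -0.89. The authors' values gave -0.38 for Agbl3, -0.35 for Tmem59l, -0.31 for Ptger4, -0.22 for Rsf1, -0.34 for Polb, -0.495 for Foxd3, -0.44 for Prss40 and -0.18 for Tmem138. Zfp386 and Trpc5 were detected on no treated array and were at least 1.56-fold and 1.62-fold lower in the background-corrected values, while the authors' values gave log2 fold changes of -0.298 and -0.34. None of these passed the threshold.

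**Figure D2:**
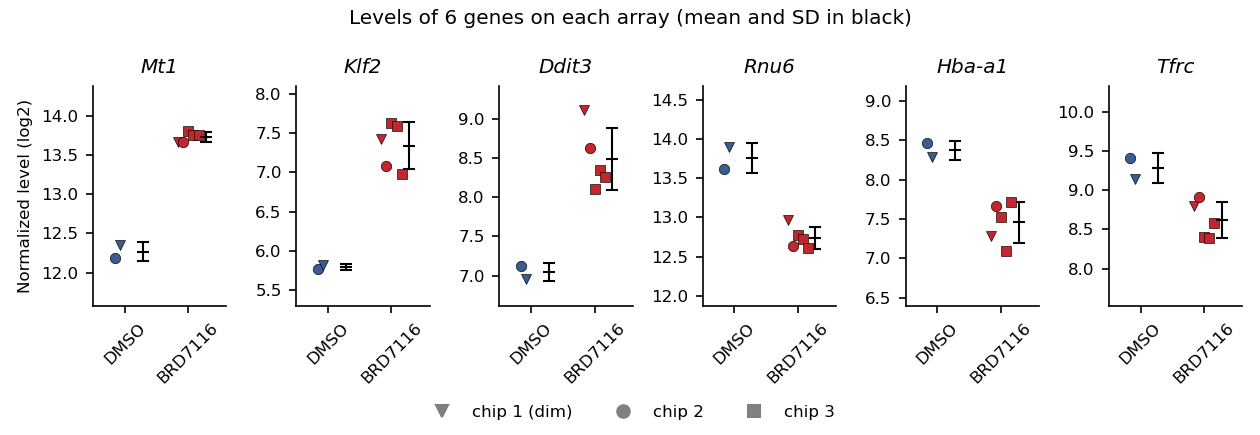
Normalized log2 level of Mt1, Klf2, Ddit3, Rnu6, Hba-a1 and Tfrc on each array; a marker is 1 array, its shape the chip and its colour the group, and black bars are the group mean and SD (n = 5 BRD7116, n = 2 DMSO). Every panel spans the same log2 range. The treated arrays lie on one side of both controls in each panel, and no gene passed the adjusted threshold.

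Across 6969 genes and unnamed probes tested with limma, 0 passed an adjusted p of 0.05. At an unadjusted p under 0.05 there were 493, of which 235 were higher and 258 lower, where 348 would be expected with no effect. Among all 6969, the 5 treated arrays lay on one side of both controls for 11.1%, where chance gives 9.52% if the 7 arrays are exchangeable, which the shared chips make doubtful. Mt1 passed under 10 of 24 alternative settings, with adjusted p from 2.28e-05 to 0.9995 over all of them. Leaving out DMSO replicate 1, which left the dim array as the only control, brought the count past the threshold to 609. At an unadjusted p under 0.05, leaving out this array gave 857 higher and 779 lower genes, and leaving out DMSO replicate 2 gave 52 and 68. With median scaling in place of quantile normalization the median of all genes was 0.55 on the log2 scale, against 0.05 before, and there were 26 higher and 0 lower genes at an unadjusted p under 0.05.

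Among regulators of leukemia stem cells fixed in advance, none passed the threshold. Meis1, a homeobox cofactor of leukemic self-renewal, had a log2 fold change of 0.23 (standard error 0.19), and its partner Hoxa9 had -0.51 (standard error 0.25). The mean of the Hoxa9 probes gave 0.083 instead. Mef2c had 0.51 (standard error 0.22), which became 0.80 without DMSO replicate 1 and 0.22 without DMSO replicate 2. Without the same arrays Hoxa9 had -0.92 and -0.10, and Meis1 had 0.39 and 0.068. Myb, detected on 1 array of each group, had 0.03 (standard error 0.25). Cebpe, a factor of granulocyte differentiation, had 0.13 (standard error 0.16). Itgam was detected on 2 treated arrays and no control, which gave no bound above 1. Hoxa10, Myc and Cd34 were detected on no array, and no probe carried the symbol Kit. Hoxa9 and Meis1 differed in sign between the chips, with -0.89 and 0.64 within the dim chip and 0.13 and -0.08 within the second chip.

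Of 43 gene lists with at least 3 measured members, camera called 2, 1 higher and 1 lower. The higher list held genes that respond to inhibitors of histone deacetylases together with replication-independent histone genes. Of its 12 measured members, 9 had a higher and 3 a lower mean with BRD7116, with a median log2 fold change of 0.36 and an adjusted p of 0.0195. With an estimated correlation the adjusted p = 0.566. No member passed over all genes tested, and 2 passed when adjusted over the list alone, Mt1 and Klf2. The histone variant gene H2az1, the other abundant member, had a log2 fold change of 0.36 (standard error 0.31), which became -0.12 without DMSO replicate 2. The list median was 0.35 within the dim chip and 0.29 within the second chip, and with chip as a block it was 0.25 with an adjusted p of 0.0396 (0.833 with an estimated correlation). The median was 0.15 with the authors' values and 0.17 without background correction. Leaving out BRD7116 replicate 1 or DMSO replicate 1 ended the call, with medians of 0.48 and 0.62 and adjusted p of 0.164 and 0.511, in a range of 0.000202 to 0.566 over all alternatives. Without DMSO replicate 2 the median was 0.18.

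The lower list held markers of red cell precursors. Only 3 of its 21 genes were measured, and all 3 had a lower mean with BRD7116, with a median log2 fold change of -0.66 and an adjusted p of 0.0135. With an estimated correlation the adjusted p = 0.566. When adjusted over the list alone, 2 members fell and 0 over all genes tested. These were Hba-a1 and Tfrc, the transferrin receptor, whose log2 fold change was -0.66 with a standard error of 0.21. The remaining member, Trim10, had -0.38 (standard error 0.23) and was named after its value was seen. Leaving out 1 array gave Trim10 -0.76 to -0.29 where it was still measured. Trim10 lay close to background, with mean levels of 5.15 treated and 5.52 control, and only 2 members were detected on all 7 arrays. Without BRD7116 replicate 5 or DMSO replicate 1 Trim10 failed the detection filter, so the list could not be tested. The list median was -0.34 within the dim chip and -0.75 within the second chip, and with chip as a block it was -0.42 with an adjusted p of 0.113. With the authors' values the median was -0.40. Without BRD7116 replicate 1 Hba-a1 had -0.88, Tfrc -0.70 and Trim10 -0.43. Leaving out BRD7116 replicate 1 gave an adjusted p of 0.0970, in a range of 6.22e-05 to 0.566 over all alternatives. With no detection filter, which brings in the members near background, the median was -0.0064 and the adjusted p was 0.461.

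Lists of metabolic and stress genes came next and did not pass. For enzymes of cholesterol synthesis, 11 of 14 measured members had a lower mean, the median was -0.33 and the adjusted p was 0.0612. Fdps, which makes farnesyl diphosphate, had a log2 fold change of -0.51 (standard error 0.18) and Hmgcs1 had -0.11 (standard error 0.17). This list passed in 12 of 27 alternative settings, among them chip as a block, where its adjusted p was 0.0441 (range 0.00409 to 0.644). With an estimated correlation its adjusted p was 0.566 over the 7 arrays and 0.833 with the block. Its median was -0.17 without BRD7116 replicate 1 and -0.10 with the authors' values. For targets of ATF4 in the integrated stress response, 24 of 31 members had a higher mean, the median was 0.19 and the adjusted p was 0.113. This list passed in 6 of 27 alternative settings (range 0.00809 to 0.697), among them the fit without DMSO replicate 2 (0.0205) and both fits without the dim chip (0.0126 and 0.00809). With an estimated correlation these 3 fits gave 0.358, 0.61 and 0.612, and the 7 arrays gave 0.566. Ddit3 passed when adjusted over the list alone, while the amino acid transporter gene Slc7a5 had 0.19 (standard error 0.19) and Gars -0.10 (standard error 0.26). For NF-kB and inflammatory genes, 11 of 14 had a higher mean, the median was 0.23 and the adjusted p was 0.113, with Ccl9 at 0.42 (standard error 0.18) and Tnfaip2 at 0.17 (standard error 0.21). When 1 array was left out, the median was 0.19 to 0.41, Ccl9 had 0.27 to 0.56 and Tnfaip2 0.13 to 0.28. The NF-kB median was -0.14 relative to the shift of all genes under median scaling and -0.017 with no detection filter, and the list passed in 2 of 27 alternative settings. With an estimated correlation the NF-kB list had 0.566 and the ribosomal list 0.729. For cytosolic ribosomal proteins the median was 0.11 over 35 members and the adjusted p was 0.144, and the list passed in 5 of 27. Its median was 0.063 to 0.19 when 1 array was left out and 0.049 to 0.38 over all alternatives. No member of the cholesterol, NF-kB and ribosomal lists passed when adjusted over the list alone.

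**Figure D3:**
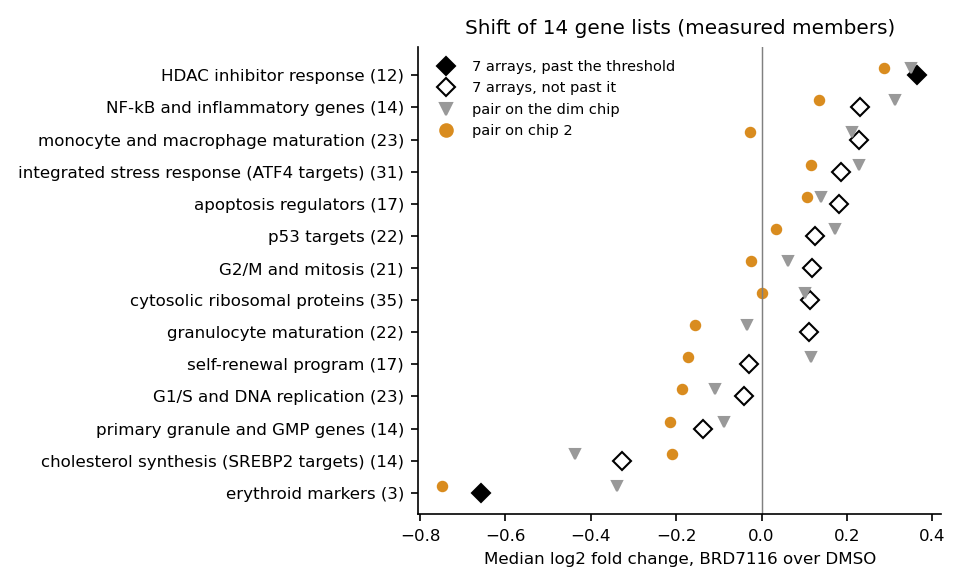
Median log2 fold change (BRD7116 over DMSO) of 14 gene lists, with the number of measured members in parentheses; diamonds are the fit over 7 arrays, filled where camera's adjusted p was under 0.05, triangles the pair on the dim chip and circles the pair on chip 2. The filled lists are at 0.36 and -0.66, and neither passed with an estimated correlation.

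No list of differentiation, self-renewal or cell cycle genes was called in the comparison as set. With detection required on all arrays, the monocyte and macrophage list was called higher (median 0.28, adjusted p = 0.0371, with an estimated correlation 0.577), and without DMSO replicate 2 its median was -0.021 and its adjusted p 0.923. Without DMSO replicate 2, the primary granule list (median -0.23, adjusted p = 0.0205) and the DNA replication list (median -0.21, adjusted p = 0.0204) were called lower, and with an estimated correlation these had 0.358 and 0.686. The primary granule list was also called lower without the dim chip when the other arrays were renormalized (adjusted p = 0.0396, with an estimated correlation 0.61), and not with the normalization over 7 arrays (adjusted p = 0.0684).

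Self-renewal genes had a median log2 fold change of -0.03 over 17 members (adjusted p = 0.546), with Lmo2 at 0.14 and Hoxa5 at -0.12. Primary granule genes of granulocyte-monocyte progenitors had a median of -0.14 over 14 members (adjusted p = 0.515), with the protease genes Prtn3 at -0.13 and Ctsg at -0.15. Granulocyte maturation genes had a median of 0.11 over 22 members (adjusted p = 0.849), with S100a8 at -0.25 and Stfa1 at 0.11. Genes of monocyte and macrophage maturation had a median of 0.23 over 23 members (adjusted p = 0.379), with the galectin gene Lgals3 at 0.51 and Ncf4 at -0.06. DNA replication genes had a median of -0.04 and a mean of 0.05 over 23 members (adjusted p = 0.599), with Mcm4 at -0.21 and Mcm5 at 0.09. Mitotic genes had a median of 0.12 over 21 members (adjusted p = 0.782), with Cenpa at 0.12 and Prc1 at 0.18. The p53 targets had a median of 0.13 over 22 members and the apoptosis regulators 0.18 over 17, each with an adjusted p of 0.546. These 2 medians were 0.012 and 0.034 without DMSO replicate 2, and 0.21 and 0.29 without DMSO replicate 1. In the same order, the other medians without DMSO replicate 2 were -0.13, -0.23, -0.066, -0.021, -0.21 and -0.15, and without DMSO replicate 1 they were 0.064, 0.19, 0.16, 0.33, 0.11 and 0.32. Relative to the shift of all genes, median scaling turned the sign for the primary granule, DNA replication and p53 lists and for Hoxa5, Prtn3, Ctsg, Ncf4, Mcm4, Hmgcs1, Gars and Myb.

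The spread between the arrays and their small number limited the precision. The median residual SD per gene was 0.33 over the 7 arrays and 0.18 over the 5 arrays outside the dim chip, where the single control adds no spread. The median half-width of the 95% confidence interval of a log2 fold change was 0.62, and 0.48 for the 2714 genes detected on all 7 arrays. Before adjustment, a gene passed only where its estimated difference exceeded the half-width of its own interval. Genes with narrow intervals passed at estimates smaller than the median half-width.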

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

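Of the tests weighed here, only the count over other splits of the arrays without a block was set before its result was seen. The others were chosen after the results were seen.

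Among the 5 treated arrays, 1 array stood apart from the other 4 for 6 of 55 values examined, where chance would give about 2.8. The gap to the nearest array, as a share of the whole range, was 0.809 for Tmem11 (BRD7116 replicate 5, 6.32 against 6.81 to 6.93), 0.764 for Mcm5 (replicate 2), 0.715 for Tnfaip2 (replicate 2), 0.774 for H2az1 (replicate 1, 9.85 against 10.4 to 10.6), 0.783 for Mef2c (replicate 3, 8.25 against 7.82 to 7.91) and 0.735 for Junb (replicate 4). Only 1 of the 6 was the treated array on the dim chip.

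The first pattern was the absence of any gene past the adjusted threshold. The median residual SD per gene was 1.84 times as large over the 7 arrays as over the 5 arrays of the other chips, so spread added by the dim chip may account for part of it. Outside the dim chip 1 control remained and was fitted exactly, so the ratio also reflects the lost spread between controls. With chip as a block the median residual SD over the 7 arrays was 0.22. Renormalized without the dim chip, however, the fit of 4 arrays against 1 also called 0 genes, with a smallest adjusted p of 0.119. With the normalization over 7 arrays kept, it called 1 gene, Mt1, at an adjusted p of 0.0270. Of the 21 ways to split the 7 arrays into 5 and 2, 2 gave at least the 493 genes at an unadjusted p under 0.05 of the real split, so chance could not be excluded. The other was the split of the dim chip from the rest, with 2895 such genes and 1955 past the adjusted threshold, which points to the chip as the main structure of these samples. With chip as a block that split cannot be fitted, and the real comparison gave 900 such genes. Splits that mirror each other within the chips are then the same model and were counted once. Of the 17 so counted, 1 gave as many, the real one, and the highest of the others gave 692. These splits are too few for a share under 0.05.

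The second pattern was the higher list of genes responsive to histone deacetylase inhibitors. Without the dim chip its camera p was 0.00152 in the same direction, which argues against the dim chip as its whole source. That p is unadjusted and at the preset correlation. Over the 7 arrays the correlation estimated for this list was -0.061, with a camera p of 0.0173 and an adjusted p of 0.566. At the preset correlation the camera p was 0.000906. A negative correlation does not raise the p, so the rise came from the fewer degrees of freedom used when the correlation is estimated. Over the 7 arrays fry called the list, with an adjusted p of 0.00675. Without the dim chip the list was not called with an estimated correlation, but with 3 residual degrees of freedom that test could hardly call any list. Without Mt1 and Klf2 the remaining 10 members had a camera p of 0.116 and a median log2 fold change of 0.31, with 7 higher, so these 2 genes may carry the call. Taking out the strongest members weakens any list, and both genes also respond to other stimuli. An action of BRD7116 on histone deacetylases stays an untested hypothesis.

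The third pattern was the lower list of red cell markers. Without the dim chip its camera p was 5.43e-05, which argues against the dim chip as its whole source. That p, too, is unadjusted and at the preset correlation. Over the 7 arrays the correlation estimated for these 3 genes was 0.39, with a camera p of 0.0416 and an adjusted p of 0.566. There fry did not call the list, with an adjusted p of 0.0895. Without the dim chip the list was not called with an estimated correlation either, under the same limit. Fewer erythroid cells in the treated wells may be a source. Hba-a1 (mean level 7.46 treated and 8.38 control) and Tfrc were both lower, and Tfrc, which other dividing cells express too, differed by less. Trim10, the remaining marker, however differed by less than Tfrc (-0.38 against -0.66), though it lay close to background. The difference of Hba-a1 minus that of Tfrc was -0.26 on the log2 scale with a standard error of 0.21. That margin is little over 1 standard error and depends on the processing. The authors' values gave -0.46 for Hba-a1 and -0.40 for Tfrc, and chip as a block gave -0.90 and -0.42. The labels name no sort that would remove such cells. Tfrc is also in the lists of metal response genes and of Myc targets. The beta globin Hbb-bt and the erythroid genes Alas2, Car2 and Klf1 were detected on no array, so the controls too showed few markers of such cells. A direct effect of the compound on Hba-a1 and Tfrc stays open.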

How the results depend on the processing

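The 2 settings that leave out the dim chip, and the estimated correlation within alternative fits, were chosen after the data were seen. The count of genes past the threshold was 1 under normexp without detection p-values, cyclic loess, the authors' values, no detection filter, detection on all arrays and chip as a random block (Mt1 each time). It was 2 without background correction and with a trended robust prior (Mt1 and Rnu6), 0 to 609 when 1 array was left out, and 0 in the other settings chosen beforehand. Without the dim chip it was 0 after renormalization and 1 (Mt1) with the normalization over 7 arrays.

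The count of lists called was 4 without background correction, with the authors' values, with chip as a random block and without the dim chip under the normalization over 7 arrays, 5 with cyclic loess and without the dim chip after renormalization, and 6 with detection on all arrays. It was 1 with median scaling, fry and only the chips that hold both groups, and 0 with array weights, an estimated correlation and ranks. Leaving out 1 array gave 0 to 6, with 0 without BRD7116 replicate 1 or DMSO replicate 1, 1 without BRD7116 replicate 5 and 6 without DMSO replicate 2. The histone deacetylase inhibitor list kept its direction in 27 of 27 settings and passed in 21. The erythroid list kept it in 22 of 22 and passed in 13, and 5 settings left it under 3 members.

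The replicate numbers were not taken as pairs. Deviations from the group means correlated at -0.52 and -0.32 between equal numbers, but with 2 controls these only mirror the 0.52 and 0.32 within chips. The check therefore cannot tell whether equal numbers shared a culture or animal. The fit with the replicate number as a block called 0 genes and 0 lists, with 1 residual degree of freedom.

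Of 1200 values of 52 genes in the text, 42 changed direction, and of 454 values of 17 lists, 29 did in camera's direction. The cause was not tested. With chip as a fixed block and with the replicate number as a block, 6 genes had values of -0.0074 (Lmo2), -0.11 (Stfa1), 0.076 (Ncf4), -0.0035 (Cenpa), 0.25 (Gars) and -0.026 (Tnfaip2). With only the chips that hold both groups these were -0.0075, -0.096, 0.075, -0.0016, 0.24 and -0.019. With chip as a random block Stfa1 had -0.039, Ncf4 0.029 and Gars 0.13. Median scaling, relative to the shift of all genes, gave Hoxa5 0.17, Prtn3 0.15, Ctsg 0.18, Ncf4 0.18, Mcm4 0.040, Hmgcs1 0.13, Gars 0.097 and Myb -0.57. Without the dim chip Hmgcs1 had 0.011 and Myb -0.30, and with the normalization over 7 arrays 0.012 and -0.26. The mean of a gene's probes gave Hoxa9 0.083, cyclic loess Myb -0.070 and array weights Myb -0.090. Leaving out 1 array gave Hoxa5 -0.28 to 0.031, Hmgcs1 -0.24 to 0.012, Gars -0.25 to 0.055, H2az1 -0.12 to 0.85 and Myb -0.22 to 0.092.

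For lists, the values are medians, which can keep their sign where camera's direction turns. Granulocyte maturation had 0.087 with cyclic loess, 0.10 with detection p under 0.01, -0.0053 with detection on all arrays, -0.066 with chip as a fixed block or the replicate number as a block, -0.00060 with chip as a random block, -0.19 with only the chips that hold both groups, 0.044 without the dim chip and -0.011 with the normalization over 7 arrays. Mitosis had 0.090 with cyclic loess, 0.13 with detection p under 0.01 and -0.033 in both fits without the dim chip. Median scaling gave 0.050 for primary granule, 0.090 for DNA replication and -0.22 for p53 genes, and array weights gave -0.059 for DNA replication. Detection on all arrays gave -0.0024 for self-renewal, -0.47 for immediate early and -0.070 for short-lived transcripts, and detection p under 0.01 gave -0.030 for the last. Leaving out 1 array gave -0.066 to 0.16 for granulocyte maturation, -0.21 to 0.11 for DNA replication, -0.15 to 0.32 for mitosis, 0.047 to 0.33 for immediate early and -0.14 to 0.11 for short-lived transcripts. Other genes of the naming rule changed direction in 166 of 1464 values and other lists in 64 of 677.

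None of the alternatives was left unrun. Low signal over background on the dim chip limits what the comparison can show, since fewer genes were detected there.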

Other observations

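Markers of other blood lineages were mostly below detection in these cells. So were most probes on the array, since 8613 of 25697 were detected on at least 2 arrays. Of the listed genes with a probe, 1 of 15 B lineage markers and 2 of 22 T and NK lineage markers were detected on at least 2 arrays. The counts were 3 of 16 for erythroid, 3 of 15 for megakaryocyte and platelet, 4 of 17 for dendritic cell, 3 of 23 for stromal and endothelial, and 6 of 18 for mast cell, basophil and eosinophil markers. In the last group 4 were detected on all 7 arrays, with Prg2 at a mean log2 level of 10.6 and Hdc at 10.3 in the treated arrays. By contrast, 14 of 15 primary granule genes of granulocyte-monocyte progenitors and 22 of 31 granulocyte maturation genes were detected, and 12 of each on all 7 arrays.

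Transcripts with short half-lives did not move one way. In the list of immediate early genes, Klf2 and Klf6 (log2 fold change 0.77, standard error 0.21) passed as higher when adjusted over the list alone, and Junb (-0.86, standard error 0.23) passed as lower. In the list of transcripts that decay quickly when RNA polymerase II stops, Klf6 was higher while Junb and Hexim1 (-0.72, standard error 0.22) were lower. None of the 4 passed over all genes tested, and neither list was called, with adjusted p of 0.623 and 0.910. Without DMSO replicate 1, Junb passed over all genes (adjusted p = 0.0197) and so did Klf6 (adjusted p = 0.0373), and over all alternatives their adjusted p ranged up to 1. Junb had -1.22 without DMSO replicate 1, -0.51 without DMSO replicate 2 and -0.33 with the authors' values, and Klf6 had 0.21 with the latter. Hexim1 had -0.20 there. Klf6 in the controls (mean level 5.65) and Hexim1 in the treated arrays (5.88) lay close to background.

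The list of metal-responsive genes, Mt1 included, was not called. Mt2 was detected on 2 treated arrays and no control, which gave no bound above 1. The median over 8 metal-response genes was 0.04, and the list had an adjusted p of 0.546. Leaving out 1 array gave medians of -0.03 to 0.19.

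The responses of the pair on the dim chip and the pair on the second chip were only weakly related. Across 6969 genes, which are not independent replicates, the Pearson correlation of the within-chip differences was 0.07, and it was 0.15 over the 2714 genes detected on all 7 arrays.

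The 26 lists not described one by one had medians from -0.24 to 0.57 and adjusted p from 0.247 to 0.982, and none was called in the comparison as set. With detection required on all arrays, the list of lysosome and autophagy genes was called higher (median 0.14, adjusted p = 0.0485), and with an estimated correlation its adjusted p was 0.577.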
